A study of Arabidopsis thaliana with 18 samples.

How the data were processed

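Gene expression was measured in leaves of Arabidopsis thaliana with 18 Affymetrix arrays, 1 per sample. Per the labels' protocols, 2-week-old plants were held in 150 mM NaCl for 24 hours and then given a methanol extract of the brown alga Ascophyllum nodosum (MEA), its ethyl acetate sub-fraction (EAA), or 0.1% aqueous methanol as the control, and each labelling reaction started from 10 µg of total RNA. The 6 groups of 3 arrays are the salt reference, EAA and MEA, each on day 1 and day 5. The labels of the 6 reference arrays conflict: the source name gives NaCl with no extract, while the title and description give EAA. The grouping follows the source name, so every comparison with the reference rests on that label. The titles call the 3 samples of a group biological replicates. They do not say whether separate plantings were used, so p-values rest on the spread between samples as labelled, pooled over the 6 groups.

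The deposited values are log2 array signals, as judged from their range in every column. Per the submitters' processing notes the tool was MAS5, with no version; the normalization, the scaling and the log step are not given in the sources used here. The lowest values and the narrow low end look unlike plain MAS5 output, so which summary method made them stays open. The values were used as deposited, and no array was rescaled for the results reported first. The table held 22810 probe sets, of which 64 were controls. Gene names came from the platform annotation, updated through a RefSeq gene table of assembly TAIR10.1. In that annotation 13513 probe sets had 1 gene, 503 had several and 8794 were unnamed here; 13436 of those with 1 gene matched the RefSeq table, and 1579 had a symbol other than the locus code. No coordinates are given, since the files name no genome build.

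Probe sets were kept where the mean log2 signal over the 18 arrays reached the 40th percentile of the 22746 non-control probe sets (4.01), which left 13648. A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 12 residual degrees of freedom and a median of 3.2 prior degrees of freedom. All 11 contrasts came from this fit, so 1 spread per probe set, common to the 6 groups, enters every p-value. The median SD was 0.337 with MEA on day 5 and 0.126 to 0.201 in the other groups. P-values of contrasts with the MEA day 5 group are therefore likely too small, and those of the other contrasts may be too large. P-values were adjusted by the Benjamini-Hochberg method within a contrast, and an adjusted p under 0.05 was the threshold. Differences are on the log2 scale with the standard error (SE) of the fit, for 3 arrays against 3. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

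Before the data were examined, 26 gene lists with 413 members were fixed; 53 members had a named probe set, 5 more were left out because the annotation gave another symbol, and 7 lists had the 3 measured members a set test needed. A further 19 families were formed from gene symbols once the annotation had been read and before any test, and 17 were tested. Lists were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation and with fry, adjusted over 77 tests for the fixed lists and 187 for the families. The genes named in the text are, per contrast, the 10 largest rises and 10 largest falls among probe sets past the threshold that pair with 1 gene with a symbol and in which all 3 arrays of a group lay beyond all 3 of the other. Up to 4 members of each fixed list with the smallest adjusted p were added, of which the text may leave some out. Where fewer than 5 probe sets passed, the 5 with the smallest p were taken. A gene with several probe sets was represented by the one with the highest mean signal. RD29A, RD29B, RAB18 and P5CS1, meant as checks of the salt response, are unnamed here.

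The model was tested on simulated data with the real overall means and common spread of 13648 probe sets, 200 of them changed. For EAA against the reference on day 1 it recovered 10% of changes of 0.5 on the log2 scale, 56% of changes of 1, 94% of changes of 2 and 100% of changes of 3, with 5 false calls among 135 (3.7%). For EAA against the reference on day 5 it recovered 78% of changes of 1, and for MEA against the reference on day 1 it recovered 72%. False calls numbered 7 among 147 (4.8%) for EAA on day 5, 10 among 147 (6.8%) for MEA on day 1, 4 among 142 (2.8%) for MEA on day 5 and 10 among 143 (7%) between the days in the reference. The simulated groups all had the same spread, while the real median SD ran from 0.126 (EAA on day 1) to 0.337 (MEA on day 5). These rates therefore do not carry over to contrasts with the MEA day 5 group. The common spread also includes the MEA day 5 arrays. The EAA, MEA and reference groups of day 1 had median SDs of 0.126, 0.137 and 0.134. For the other contrasts the rates hold for the simulated spread and may differ in the real groups. The number of arrays limits the precision. The alternatives tried were quantile normalization, median centring, no filter or a 60th percentile filter, an offset of 16, no trend, a robust prior, a fold minimum of 2, a fit on the compared groups alone, a replicate block, and leaving out each array in turn. Fits without the MEA day 5 group, without that group and EAA day 5 replicate 1, with the 9 arrays of day 1 alone, and with the MEA day 5 group represented by its second array were chosen after seeing the data. Calls of list members were checked under both scalings: all 188 kept their sign.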

Results

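The series asked which genes respond to extracts of the brown alga Ascophyllum nodosum in salt-stressed Arabidopsis leaves. It held 18 arrays in 6 groups of 3: the salt reference, the ethyl acetate sub-fraction (EAA) and the methanol extract (MEA), on day 1 and on day 5. The 6 arrays of the salt reference are labelled NaCl in their source name but EAA in their title, and are called the reference here by the source name. Within each day 1 group the arrays correlated at 0.986 to 0.993 across probe sets, which are not independent replicates. The day 5 reference arrays correlated at 0.96 to 0.986, the day 5 EAA arrays at 0.958 to 0.984 and the day 5 MEA arrays at 0.836 to 0.964. The first principal component held 69.2% of the variance and separated the days, except that MEA day 5 replicates 1 and 3, at -26.6 and -37.5, lay near the day 1 arrays (-42.5 to -32.9). MEA day 5 replicate 2 lay at 67.6, within the range of the other day 5 arrays (37.9 to 74.2). On the second component reference day 5 replicate 2 lay at 42.1, against 1.9 and 10.2 for the other reference arrays of day 5.

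**Figure D1:**
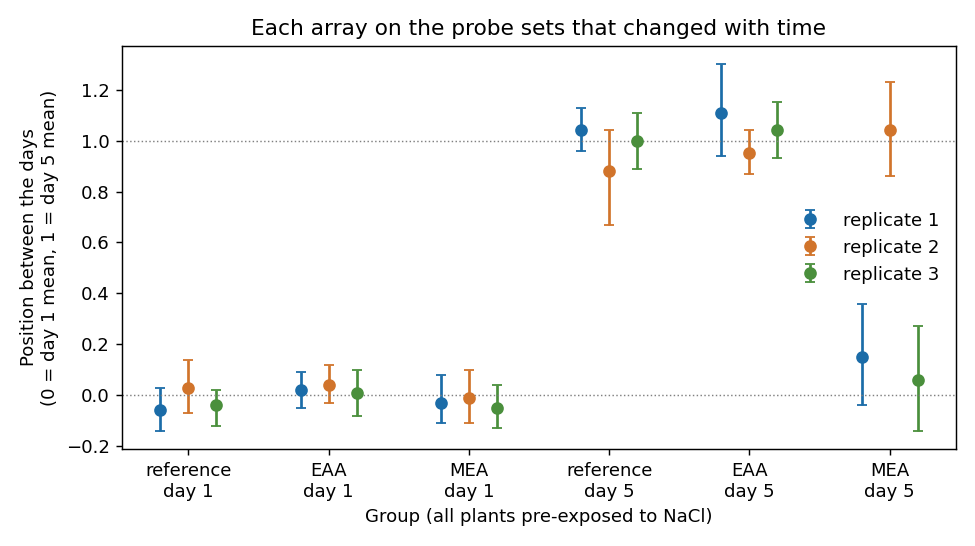
Position of each array between the days (vertical axis, no unit; 0 is the mean of the reference and EAA arrays of day 1 and 1 that of day 5) for the 6 groups, as the median over 1492 probe sets that changed with time, with bars from the first to the third quartile. MEA day 5 replicates 1 and 3 sit at 0.15 and 0.06, while MEA day 5 replicate 2 sits at 1.04.

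From day 1 to day 5 in the reference leaves, large falls among genes with a symbol were those of PORB, COR27 and TUB5, and a large rise was that of AFR. Where a group mean lay under 4.01, the filter value, the signal was near the low end and the size of the difference is uncertain; in this contrast that held for COR27 (3.98 on day 5), GH3.3 (3.86 on day 5), HYH (3.74 on day 1), TRY (3.83 on day 1), and CCR2 and XTH19 (3.97 each on day 1). PORB (AT4G27440), a protochlorophyllide oxidoreductase of chlorophyll synthesis, fell by 5.27 on the log2 scale (SE 0.97, adjusted p = 0.00103, n = 3 per day). COR27 (AT5G42900), a cold-regulated gene, fell by 4.69 (SE 0.44), the beta-tubulin gene TUB5 fell by 4.65 (SE 1.02) and the beta-glucosidase gene BGLU44 fell by 4.27 (SE 0.90). WLIM2a, which encodes an actin-binding LIM protein, fell by 3.84, and DPE1, a plastid enzyme of starch breakdown, fell by 3.75. LCR69 (-3.45), Fes1B (-3.32), the chloroplast lipocalin gene CHL (-3.23) and COR15B (-3.11) also fell. AFR (AT2G24540), an F-box gene of far-red light signalling, rose by 3.93 (SE 0.53, adjusted p = 8.7e-05). The U-box ubiquitin ligase gene PUB19 rose by 3.14, the wax ester synthase gene WSD1 by 2.84 and the asparaginase gene ASPGB1 by 2.76. TRY and GIS, regulators of trichome formation, rose by 2.39 and 2.31, and HYH, a bZIP gene of light signalling, rose by 2.29. SIS, MGL (methionine gamma-lyase) and CCR2 (AT1G80820, a cinnamoyl-CoA reductase gene) rose by 2.36, 2.35 and 2.22.

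Among the fixed lists in the reference, 3 of 5 ABA and dehydration genes fell: COR15A by 1.08, COR15B by 3.11 and LTI30 by 1.23, also 3 when adjusted over the list alone. The differences of COR47 (-0.27) and LEA4-5 (1.92, SE 1.17) did not pass. Of 4 antioxidant enzyme genes 3 rose, the glutathione reductase genes GR1 (1.53) and GR (0.71) and the ascorbate peroxidase gene SAPX (0.83), again 3 when adjusted over the list alone, while TAPX stood at -0.72 without passing. Of 6 flavonoid genes 1 rose, UGT78D2 by 1.76, and of 3 auxin genes 1 fell, GH3.3 by 2.88, with 2 falling when adjusted over the list alone. The starch synthesis gene APL3 rose by 1.68, XTH19 of the cell wall list by 2.18 and the heat shock list member AT5G48570 by 2.36, and the clock gene GI fell by 2.25. No fixed list passed camera for time in any of the 3 treatments. With fry, which asks whether a list changed at all and not whether it changed more than other genes, the antioxidant list was higher (adjusted p = 0.002) and the auxin list lower (0.033) in the reference. Among the families, 5 of 7 tubulin genes fell in the reference, TUB9 by 1.75, TUA6 by 1.04 and TUB6 by 1.06 beside TUB5 and TUB1, whose day 5 mean of 3.22 was too low for a size to be given, and 4 of the 5 changed beta-glucosidase genes fell, while BGLU40 rose by 1.18. Beta-glucosidases passed fry there (adjusted p = 0.0143) and not camera (0.125). Of 6 SWEET sugar transporter genes SWEET2 rose by 1.82, SWEET1 by 1.51, SWEET11 by 1.44 and SWEET13 by 1.18, and SWEET17 fell by 0.55. In all 4220 of 13648 probe sets passed, 1919 higher and 2301 lower on day 5 (45.5% higher), of which 793 and 969 changed at least 2-fold. With each array centred on its median the share higher was 57.1%, so which direction held more calls turned with the scaling.

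With EAA the same contrast of days gave 4975 probe sets, 2142 higher and 2833 lower (43.1% higher, and 58% with median centring). PORB fell by 5.42 (SE 0.97, adjusted p = 0.00115). BGLU44 (-4.87), TUB5 (-4.77), COR27 (-3.90), WLIM2a (-3.87), LCR69 (-3.75) and DPE1 (-3.40) fell as well. Falls were also measured for DRT100 (-3.38), the vacuolar sugar transporter gene TMT1 (-3.37) and the methionine sulfoxide reductase gene MSRB6 (-3.26). The day 5 means of COR27 (3.86) and DRT100 (3.89) lay under 4.01, so the sizes of their falls are uncertain. Among genes with a symbol, LEA4-5 (AT5G06760), a late embryogenesis abundant gene, rose by 4.02 (SE 1.17, adjusted p = 0.0159), from a mean log2 signal of 6.31 ± 0.17 to 10.33 ± 0.36 (SD, n = 3). SAG29 (AT5G13170), a senescence-associated sugar transporter gene, rose by 3.96 (SE 1.03). AFR rose by 3.41, MGL by 3.04, the co-chaperone gene Fes1A by 2.77, CCR2 by 2.66, PUB19 by 2.53, SIS by 2.52 and WSD1 by 2.48. The co-chaperone gene Hop3 stood at 5.92 ± 1.04 on day 5 and at 3.14 ± 0.01 on day 1 (SD, n = 3), at the low end of the signals, so the size of its rise is not given. EAA day 5 replicate 1, which enters this contrast, had a higher actin 3' to 5' difference (2.78) than the reference arrays (1.67 to 2.03). All 4 antioxidant genes passed, GR1 (1.4), SAPX (1.10) and GR (0.54) higher and TAPX lower (fell by 1.07), and 4 when adjusted over the list alone. Of 13 serine carboxypeptidase-like genes 8 fell, among them scpl35 by 2.15 and SCPL45 by 1.61, with 9 when adjusted over the list alone; the family passed camera (adjusted p = 0.00378) and fry (0.0143), with an adjusted p = 0.953 with an estimated correlation. Fry was also passed by the antioxidant list (adjusted p = 0.00321), beta-glucosidases (0.0143) and trichome birefringence-like genes (0.0185), which did not pass camera.

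With MEA fewer probe sets passed between the days, 535 (217 higher, 318 lower, 40.6% higher, against 58% with median centring and 54.8% with quantile normalization). COR27 fell by 3.86 (SE 0.44, adjusted p = 0.000593), and so did LCR69 (-2.65), the pyruvate decarboxylase gene PDC2 (-1.48), MAP1C (-1.32), TUB9 (-1.31) and BGLU25 (-1.09). AFR rose by 2.08 (SE 0.53), the auxin glucosyltransferase gene IAGLU by 1.23, HYH by 1.21 (from a low mean of 3.79), PUB25 by 1.21 and PPDK, pyruvate phosphate dikinase, by 1.14. The gibberellin receptor gene GID1A fell by 0.92 and the starch-related gene PWD by 1.09. No fixed list member passed over all genes, and 3 of 5 ABA and dehydration genes were lower and 3 of 4 antioxidant genes higher when adjusted over the list alone. Tubulins (adjusted p = 0.0198), beta-glucosidases (0.0198), serine carboxypeptidase-like genes (0.0311) and the chloroplast-encoded genes (1.64e-07, median 0.25) passed camera, each with an adjusted p = 0.953 with an estimated correlation. Of these, beta-glucosidases passed fry (adjusted p = 0.0196), while tubulins (0.209), serine carboxypeptidase-like genes (0.247) and chloroplast-encoded genes (0.259) did not; the antioxidant list passed fry alone (0.00856). These values stand beside the spread of the MEA day 5 arrays, whose median SD of 0.337 compares with 0.183 in the reference and 0.201 with EAA on day 5. The actin 3' to 5' difference was 2.88 in MEA day 5 replicate 1 and 2.30 in MEA day 5 replicate 3, against 1.67 to 2.03 in the reference arrays. With MEA day 5 replicate 2 alone, 5168 probe sets passed, and LCR69 fell by 4.77 and PPDK rose by 1.99; leaving out 1 array at a time gave 111 (without MEA day 1 replicate 3) to 1756 (without MEA day 5 replicate 3).

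On day 1, the flavonoid and anthocyanin list was higher with EAA than in the reference. The 6 measured members had a median difference of 0.86 and a mean of 0.86 (camera adjusted p = 0.000219, but adjusted p = 0.621 with an estimated correlation and 0.393 with fry). The estimated correlation was 0.452 against the preset 0.01, so the first of these values leaves most of the members' shared variation out. DFR (AT5G42800), dihydroflavonol reductase, stood at 8.96 ± 0.64 with EAA and 7.46 ± 0.95 in the reference (SD, n = 3), a difference of 1.5 (SE 0.77). The glycosyltransferase genes UF3GT and UGT78D2 differed by 0.94 and 0.93, the malonyltransferase gene AT5MAT by 0.80, AT4G14090 by 0.78 and UGT78D1 by 0.21. None of the 6 passed over all genes, and 1, UGT78D2, passed when adjusted over the list alone (adjusted p = 0.0481). Across all genes 3 probe sets passed, none of them paired with a gene in the annotation: 1 fell by 2.03 (SE 0.24, adjusted p = 0.00666), another fell by 1.65 (SE 0.22) and the last rose by 0.84 (SE 0.13). At an unadjusted p under 0.05 limma gave 436 probe sets, against 682 expected by chance. Leaving out 1 array gave 0 to 2 calls, with 0 without reference day 1 replicate 1 or 2 or without EAA day 1 replicate 3.

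**Figure D2:**
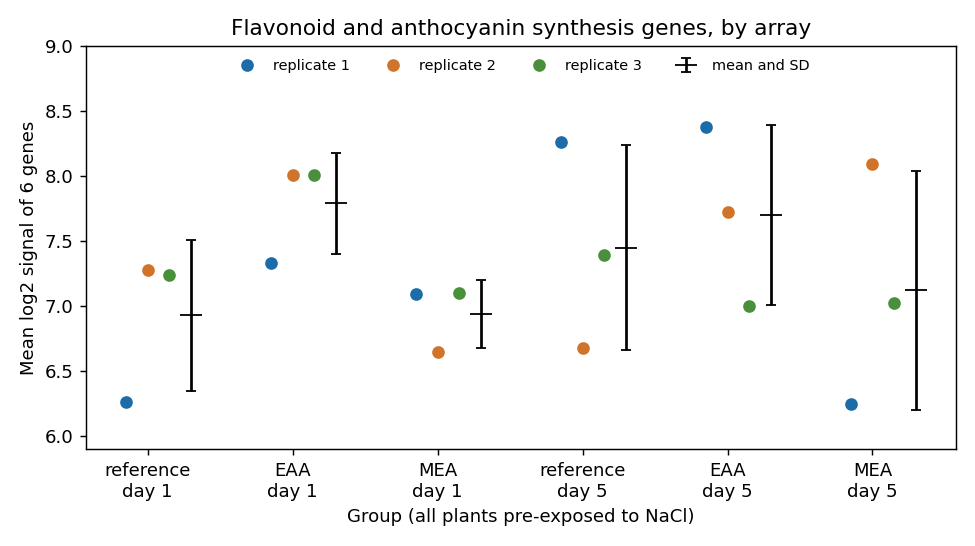
Mean log2 signal of the 6 flavonoid and anthocyanin genes (vertical axis, which does not start at 0) on each array, by group, with the group mean and SD in black (n = 3). The EAA arrays of day 1 sit at 7.33, 8.01 and 8.01, the reference arrays of day 1 at 6.26, 7.28 and 7.24 and the MEA arrays of day 1 at 7.09, 6.65 and 7.10.

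A fit on the 9 arrays of day 1 alone, chosen after seeing the data because the spread of the MEA day 5 arrays enters the common variance, gave 193 probe sets for EAA against the reference on day 1, 126 higher and 67 lower, with the 3 above among them. In that fit CSLA01 (AT4G16590), a cellulose synthase-like gene, rose by 1.52 (SE 0.14, adjusted p = 0.000865, n = 3 per group). CHIL (AT5G05270), a chalcone isomerase-like gene of flavonoid synthesis, rose by 1.32 (SE 0.19) and UGT78D2 by 0.93 (SE 0.16, adjusted p = 0.0129). The expansin gene EXPB3 rose by 0.88, the receptor kinase gene SD1-29 by 0.83, the sugar transporter gene SWEET13 by 0.80 and the sucrose phosphate synthase gene ATSPS4F by 0.70. The jasmonate methyltransferase gene JMT rose by 0.68, VTC4 of ascorbate synthesis by 0.66 and GH9C2 by 0.63. UGT85A5 fell by 0.97, COR27 by 0.91, AKINBETA1 by 0.86 and PWD, an enzyme of starch breakdown, by 0.52. A fit without the MEA day 5 group gave 25 probe sets, of which UGT85A5 (-0.97, SE 0.17, adjusted p = 0.0227) was the 1 with a symbol, and UGT78D2 did not pass there (adjusted p = 0.0764). A fit on the 6 arrays compared gave 151.

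MEA against the reference on day 1 moved no named gene past the threshold. The flavonoid list had a median of 0.07, with DFR at 0.20 and UGT78D2 at 0.05, and the ABA and dehydration list a median of 0.16, with COR15A at 0.01 and LTI30 at 0.24. IAGLU (-0.64, SE 0.18) and AT4G32190 (0.39, SE 0.11) were among the 5 smallest p-values, both with an adjusted p = 1. No probe set passed, limma gave 169 at an unadjusted p under 0.05, and 0 passed with any array left out. The 9 arrays of day 1 alone gave 1, unnamed here, which rose by 1.28 (SE 0.15). The ATG8 autophagy family (9 genes, median -0.20, camera adjusted p = 0.0148) and the chloroplast-encoded genes (69, median 0.03, adjusted p = 0.0379) passed, with an adjusted p = 0.953 and 0.973 with an estimated correlation and 0.557 and 0.924 with fry. No single member of either passed.

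EAA against MEA on day 1 compared the sub-fraction with the whole extract directly. The flavonoid list was again higher with EAA (median 0.79, mean 0.84, camera adjusted p = 0.000219, and adjusted p = 0.621 with an estimated correlation and 0.393 with fry), with DFR at 1.3, UF3GT at 1.03 and UGT78D2 at 0.87 above MEA, none of which passed alone. Over all genes 3 probe sets unnamed here passed, 1 higher by 0.93 and 2 lower (-1.52 and -1.62). With the 9 arrays of day 1 alone 107 passed, 75 higher and 32 lower. There CSLA01 was higher with EAA by 1.36 (SE 0.14, adjusted p = 0.003), the salicylate and benzoate methyltransferase gene BSMT1 by 1.22, JAL23 by 1.14, UGT78D2 by 0.87 and SD1-29 by 0.67. COR27 fell by 1.09, UGT85A5 by 0.76, the clock gene GI by 0.59, SWEET4 by 0.55 and PWD by 0.42. Without the MEA day 5 group 10 probe sets passed, none with a symbol, and UGT78D2 did not (adjusted p = 0.142). Leaving out 1 array from the fit of all groups gave 0 to 1 calls, with 0 without any EAA array of day 1 or MEA day 1 replicate 1.

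On day 5, EAA against the reference gave large differences that did not pass in the fit of all 18 arrays. LEA4-5 stood at 10.33 ± 0.36 with EAA and 7.59 ± 1.5 in the reference (SD, n = 3), a difference of 2.74 (SE 1.17). SAG29 differed by 2.18 (SE 1.03) and GH3.3 by 1.43 (SE 0.40), the last with a low reference mean of 3.86. No probe set passed (smallest adjusted p = 0.117, among others for AT1G65490 at -0.91, SE 0.15), and limma gave 1017 at an unadjusted p under 0.05. The cold and late embryogenesis family (8 genes, median 0.49) passed camera (adjusted p = 0.0198), with an adjusted p = 0.953 with an estimated correlation, 0.308 with fry and no member passing alone. Leaving out 1 array gave 0 to 4 calls, with 4 without reference day 5 replicate 1. In EAA day 5 replicate 1 the control probe sets gave a log2 difference between the 3' and 5' ends of the actin transcript of 2.78 and of GAPDH of 0.79, against 1.67 to 2.03 and 0 to 0.5 in the reference arrays.

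The fit without the MEA day 5 group, chosen after seeing the data, gave 216 probe sets for EAA against the reference on day 5, 118 higher and 98 lower. LEA4-5 rose by 2.74 (SE 0.51, adjusted p = 0.0149), APL4, a subunit gene of ADP-glucose pyrophosphorylase, by 2.30 (SE 0.38), SAG29 by 2.18 (SE 0.47) and the drought-induced gene DI21 by 2.02 (SE 0.34). The expansin-like gene EXLB1 and the auxin-conjugating gene GH3.3 rose by 1.43 each, CHI (AT2G43570, a chitinase gene) by 1.36, ZW9 by 1.21, ALDH7B4 by 0.95 and UBC32 by 0.79. IQD22 fell by 0.96, the allantoinase gene ALN by 0.95, IQD24 by 0.89, SWEET13 by 0.87 and scpl50 by 0.85. The sucrose transporter gene SWEET11 fell by 0.71, the glucosinolate transporter gene GTR2 by 0.53 and MRL7-L by 0.48. The reference means of APL4 (3.97) and GH3.3 (3.86) lay under 4.01, so the sizes of these rises are uncertain. The comparison includes reference day 5 replicate 2, whose position between the days was 0.88, against 1.04 and 1.00 in the other reference arrays of day 5. LEA4-5 and SAG29 had reference SDs of 1.5 and 1.38, and the 216 calls were not refitted without reference day 5 replicate 2. The comparison also includes EAA day 5 replicate 1 with its high actin difference. Leaving that array out as well gave 97 probe sets, 88 of them among the 216, and 6 of the 18 genes named here passed: APL4 (1.98), DI21 (2.02), EXLB1 (1.46), ALN (-1.24), IQD24 (-0.81) and SWEET13 (-0.79). The other 12 did not, among them LEA4-5 (2.55, SE 0.57, adjusted p = 0.059), SAG29 (2.12, adjusted p = 0.0959) and GH3.3 (1.44, adjusted p = 0.0627), whose differences stayed near those above. A fit on the 6 arrays compared gave 4.

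MEA against the reference on day 5 gave 1456 probe sets, 549 higher and 907 lower. The share higher was 37.7%, against 45.2% with quantile normalization and 44.4% with median centring. GH3.3 (AT2G23170) rose by 1.77 (SE 0.40, adjusted p = 0.0143, n = 3 per group), PDC2 by 1.56, the cation exchanger gene CHX16 by 1.51, UBP22 by 1.28 and CCL by 1.26. VPS20.1, UGT80B1, PIFI, UGT85A2 and SCPL49 rose by 1.11, 1.00, 0.98, 0.97 and 0.93. ASPGB1 (AT3G16150) fell by 2.43 (SE 0.61, adjusted p = 0.0226), WSD1 by 2.40, the cell wall gene XTH19 by 2.39, SWEET11 by 1.71, PPR596 by 1.66, GIS by 1.56 and SRC2 by 1.44. The chaperonin gene Cpn60beta2 fell by 1.41, SWEET2 by 1.38 and TRY by 1.37. Of the fixed lists, GR1 of the 4 antioxidant genes fell by 0.90 and AT5G48570 of the heat shock list by 2.21; 2 of 3 auxin genes were higher when adjusted over the list alone, and no list passed camera. The chloroplast-encoded genes had a median of 0.21 (camera adjusted p = 0.00378, and adjusted p = 0.953 with an estimated correlation and 0.478 with fry). Calmodulin-like genes (4 measured, median -0.84) passed fry (adjusted p = 0.0312) and not camera (0.481).

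These values include MEA day 5 replicates 1 and 3, which lay near the day 1 arrays and had actin 3' to 5' differences of 2.88 and 2.30, against 1.67 to 2.03 in the reference arrays. The median SD of the MEA day 5 arrays was 0.337, against 0.183 in the reference. With 1 spread common to all groups, the p-values above are likely too small. The GAPDH difference was 1.06 in MEA day 5 replicate 1, against 0 to 0.5. Group means under 4.01 leave the sizes uncertain for GH3.3 (3.86), CHX16 (3.80) and UBP22 (3.96) in the reference and XTH19 (3.76) with MEA. With MEA day 5 replicate 2 alone, assumed to vary like the other groups, 913 probe sets passed, of which 207 were among the 1456. Of the 22 genes named above 6 passed in that fit: GH3.3 (1.72), CCL (0.89), UGT85A2 (0.79), PPR596 (-1.39), TRY (-2.21) and XTH19, which was lower. The other 16 did not, among them ASPGB1 (-1.93), SWEET2 (-1.23), SRC2 (-1.21), SWEET11 (-0.41), WSD1 (-0.37), GIS (-0.36), GR1 (-0.10), VPS20.1 (0.80), UBP22 (0.53), PDC2 (0.39) and CHX16 (0.29). With 1 array in the group, a lost call alone does not show that a difference rested on the other arrays: ASPGB1, SWEET2 and SRC2 stayed near their size, while SWEET11, WSD1, GIS, GR1, PDC2 and CHX16 shrank. A fit on the 6 arrays compared gave 0. Leaving out 1 array gave 374 (without reference day 5 replicate 3) to 5489 (without MEA day 5 replicate 2).

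EAA against MEA on day 5 gave 526 probe sets, 257 higher and 269 lower with EAA. WSD1 was higher with EAA by 2.40 (SE 0.59, adjusted p = 0.0421), CCR2 by 2.36, Fes1A by 2.34, XTH19 by 1.79, TBL38 by 1.65 and the mitochondrial NADH dehydrogenase gene NDB2 by 1.56. UGT76E11, the peptide gene RALFL32, M10 and Phox4 were higher by 1.42, 1.32, 1.26 and 1.19. Lower with EAA were CHX16 (-1.67), PDC2 (-1.60), UBP22 (-1.18), CCL (-1.14), PIFI (-1.03), HON4 (-1.0), AILP1 (-0.98), BIM1 (-0.92) and UGT85A2 (-0.86). The chloroplast-encoded photosystem gene psbB fell by 0.53, and the 69 chloroplast-encoded genes had a median of -0.29 (camera adjusted p = 4.91e-06), the 10 nuclear photosystem genes one of -0.52 (0.0311) and the 13 serine carboxypeptidase-like genes one of -0.46 (0.0198), each with an adjusted p = 0.953 with an estimated correlation and, in this order, 0.215, 0.443 and 0.232 with fry. The MEA arrays near day 1, with actin 3' to 5' differences of 2.88 and 2.30 against 1.67 to 2.03 in the reference arrays, enter here too. With 1 spread common to all groups, the p-values of this contrast are likely too small as well. The means of XTH19 with MEA (3.76) and CHX16 with EAA (3.64) lay under 4.01, so the sizes of their differences are uncertain. With MEA day 5 replicate 2 alone 28 probe sets passed, 3 of them among the 526 and none a gene named here. The differences of WSD1 (0.37), PDC2 (-0.43) and CHX16 (-0.44) shrank there, while those of UGT85A2 (-0.69) and CCL (-0.77) stayed nearer their size and XTH19 was still higher with EAA, so for these the lost call does not show dependence on the other MEA arrays. A fit on the 6 arrays compared gave 0. Leaving out EAA day 5 replicate 1, 2 or 3 gave 5, 266 and 0 probe sets. Without MEA day 5 replicate 1, 2 or 3 the counts were 2, 5897 and 0.

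The differences of the extract effects between the days were tested as interactions. For EAA 1 probe set passed, that of AT1G65490, whose EAA effect fell by 1.66 from day 1 to day 5 (SE 0.22, adjusted p = 0.019); limma gave 650 at an unadjusted p under 0.05. The call was lost in 8 of the 12 fits that left out 1 array: without reference day 1 replicate 1, reference day 5 replicate 2 or 3, any EAA array of day 1, or EAA day 5 replicate 1 or 3. Without the MEA day 5 group, a fit chosen after seeing the data, 98 passed, 41 higher and 57 lower. There the EAA effect on GH3.3 was higher on day 5 by 2.06 (SE 0.41, with a low day 5 reference mean of 3.86), that on UGT85A5 by 1.64 and that on EXLB1 by 1.44, while the effect on SWEET13 fell by 1.67 (SE 0.22), on ATSPS4F by 1.23, on JMT by 1.03 and on IQD24 by 0.89. Leaving out EAA day 5 replicate 1 as well gave 76. The flavonoid list had a median interaction of -0.61, which did not pass (camera adjusted p = 0.222). For MEA 14 probe sets passed, 5 higher and 9 lower, none of them a gene with a symbol. The contrast includes the MEA day 5 arrays with actin differences of 2.88 and 2.30. With 1 array left out the count ran from 0 to 3104 (without MEA day 5 replicate 2). It was 0 without reference day 1 replicate 3 and without MEA day 1 replicate 2 or 3.

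The EAA and MEA responses share their reference arrays. Across genes their log2 differences correlated at 0.49 on day 1, against 0.50 in 100 simulations of unchanged groups with a shared reference, and the covariance was 0.0186 against 0.0336 simulated. On day 5 the correlation was 0.12 against 0.50 simulated, and the covariance 0.0206 against 0.0333. The simulation gave all groups 1 common spread per probe set. The median SDs were 0.126 to 0.137 on day 1, and 0.183, 0.201 and 0.337 for the reference, EAA and MEA on day 5. The simulated values therefore do not match these groups, and the gaps from them decide nothing. Leaving out MEA day 5 replicate 2 turned the day 5 correlation to -0.12, and leaving out MEA day 5 replicate 3 raised it to 0.37.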

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

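The tests in this part, except the bound on the salt response, were written after the counts or array positions they bear on had been seen. AT1G65490 stood out because the EAA effect on it differed between the days (-1.66, adjusted p = 0.019, limma), the 1 probe set of that interaction. Of 100 splits of the 12 arrays, the real one included, 3 gave at least 1 call. The others of these 3 reached the same 1 as the real split. A count of 1 that other splits match, and that became 0 in 8 of 12 fits leaving out 1 array and with a replicate block, is too small for chance to be set aside. For MEA, 14 probe sets differed between the days, and 21 of 100 splits gave as many, up to 1222, so chance was not excluded; splits with far more calls than the real one point to a structure of the arrays. The control probe sets, which enter no comparison, gave a log2 difference between the 3' and 5' ends of the actin transcript of 2.88 in MEA day 5 replicate 1, 2.78 in EAA day 5 replicate 1 and 2.30 in MEA day 5 replicate 3, above the 1.67 to 2.03 of the 6 reference arrays. The corresponding GAPDH difference was 1.06 in MEA day 5 replicate 1, against 0 to 0.5 in the reference arrays.

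MEA day 5 replicates 1 and 3 lay near the day 1 arrays. On 1492 probe sets that changed with time in the reference and with EAA, they stood at 0.15 and 0.06 of the way from day 1 to day 5. A swap between arrays of the 2 days is argued against, since 0 arrays labelled day 1 lay past the midpoint. Day 1 tissue under a day 5 label may account for the positions: 9 probe sets stood at the day 5 level in both arrays, against 0 in any pair of MEA day 1 arrays, but the actin values of these arrays keep that count from deciding, a condition set after the count was seen. The same holds for a mixture of RNA of both days (15 probe sets, against 1), and an effect of MEA itself, present in 2 of 3 arrays, stays open and untested.

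The flavonoid list was higher with EAA on day 1. A single array as the source of the whole difference is argued against: the list difference was 0.86 and stayed at 0.53 or more whichever array was left out. The 0.53 came without reference day 1 replicate 1, so that array carried a part of it. Its list mean was 6.26, against 7.28 and 7.24 in the other reference arrays of day 1. EAA day 1 replicate 1 (7.33) lay close to the latter values. Genes of this list varied together between arrays within groups (estimated correlation 0.452), so a shared shift for other reasons could enter the difference. An exact two-sided permutation test of the list mean, 3 EAA arrays against the other 6 of day 1, gave p = 0.0119, the smallest it can give, and an adjusted p = 0.0833 over the 7 fixed lists, an adjustment added once the unadjusted p was known. This adjusted p is the smallest that a list standing out alone could reach, so it could not have passed 0.05 that way, and the antioxidant and nuclear photosynthesis lists (unadjusted p = 0.0357 each) have the same 0.0833. The adjusted test therefore decides nothing. Whether such shared variation accounts for the list difference stays open beside an effect of EAA. Against the 3 reference arrays alone the exact permutation p was 0.1, also the smallest possible.

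The labels of the reference arrays conflict. If the reference plants had received no salt, genes of the ABA and dehydration list should stand higher with extract and salt; the bound was a median of at least 1 in all 4 comparisons of an extract with the reference, to be missed by more than 2 SE of the list mean on each day. On day 1 the medians were 0.08 with EAA and 0.16 with MEA, below 1 by 0.92 and 0.84, which is more than 2 SE (0.35 and 0.34). On day 5 they were 0.27 and 0.39, below 1 by 0.73 and 0.61, which is within 2 SE (1.04 and 0.70). This SE is taken over the 5 genes of the list, so the spread of the list between arrays (SD 0.4) does not enter it. All 4 medians lay below 1, but by more than 2 SE on day 1 alone. A reference without salt therefore cannot be told apart from one with salt by this list. Whether the reference plants could have been given EAA, as their titles say, was not tested; the salt values of 0.16 and 0.39 do not bear on it.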

How the results depend on the processing

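The fits without the MEA day 5 group, without that group and EAA day 5 replicate 1, with the 9 arrays of day 1 alone and with MEA day 5 replicate 2 alone were chosen after seeing the data. Probe sets passing in EAA against the reference, day 1, numbered 3; 0 with a 60th percentile filter, 0 with a replicate block, 151 on the groups compared alone, 25 without the MEA day 5 group and 193 on the day 1 arrays. For EAA against MEA on day 1 (3), these gave 1, 1, 169, 10 and 107. EAA against the reference on day 5 (0) gave 4 on the groups compared alone and 216 without the MEA day 5 group, which became 97 with EAA day 5 replicate 1 left out too, and MEA against the reference on day 1 (0) gave 1 on the day 1 arrays. MEA against the reference on day 5 (1456) gave 547 with a fold of at least 2, 0 on the groups compared alone and 913 with MEA day 5 replicate 2 alone. EAA against MEA on day 5 (526) gave 301 with no filter, 303 with a fold of at least 2, 0 on the groups compared alone, 8 with a replicate block and 28 with MEA day 5 replicate 2 alone. With a fold of at least 2, day 5 against day 1 gave 1762 in the reference, 2040 with EAA and 216 with MEA (535, with 0 on the groups compared alone and 5168 with MEA day 5 replicate 2 alone). The EAA interaction (1) gave 57 on the groups compared alone, 0 with a replicate block 98 without the MEA day 5 group and 76 with EAA day 5 replicate 1 left out too. The MEA interaction (14) gave 6 with quantile normalization, 6 with no filter, 0 on the groups compared alone, 4 with a replicate block and 318 with MEA day 5 replicate 2 alone. Fewer arrays, a stricter threshold or a different common variance enter by construction; otherwise the cause was not tested.

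For the fixed lists, the 1 call of EAA against the reference and of EAA against MEA on day 1 became 0 with an estimated correlation and 0 with fry. Fry called 2 lists between the days in the reference, 1 with EAA and 1 with MEA, where no filter also called 1. Of 187 tests of families 17 passed camera, 0 with an estimated correlation and 6 with fry, of which 2 passed camera too. Fry without regard to direction passed for 16, of which 14 were contrasts of the days. The day 1 arrays alone called 1 list for MEA against the reference and 3 for EAA against MEA. The replicate block rests on numbers that are not stated to pair the samples. On day 1, arrays of the same number correlated in their deviations at a median of 0.082, against -0.046 for different numbers. On day 5 the medians were -0.101 and 0.038. Of 9 pairs with the same number, 2 on day 1 and 3 on day 5 lay over 0.1. Between the reference and EAA on day 1 the same-number values were 0.144, 0.165 and 0.098, so a pairing there is not excluded. Leaving out 1 array at a time gave 0 to 2 calls for EAA against the reference on day 1, 0 to 4 on day 5, 0 for MEA on day 1, 374 to 5489 on day 5, 0 to 1 for EAA against MEA on day 1, 0 to 5897 on day 5, 2892 to 3766 between the days in the reference, 3281 to 4468 with EAA, 111 to 1756 with MEA, and 0 to 2 and 0 to 3104 for the EAA and MEA interactions. For fixed lists it gave 1 to 1 for both EAA comparisons on day 1, 0 to 1 for EAA on day 5, 0 to 2 between the days with MEA, 0 to 2 and 0 to 1 for the interactions, and 0 to 0 otherwise. The correlation of the EAA and MEA responses ranged from 0.40 to 0.59 on day 1 and from -0.12 to 0.37 on day 5. Among genes selected for naming in the fit of all groups, including list members that passed there, none changed sign under any alternative. Most were chosen with all 3 arrays of a group beyond all 3 of the other. For these, leaving out an array cannot turn the sign, so that outcome was fixed in advance. Over the fits leaving out 1 array, 290 checks lost the call and 6 gained one. The other 700, which include the flavonoid list mean, stayed the same. On the groups compared alone 65 lost the call, 8 gained one and 88 stayed the same. With a replicate block 31 lost it and 130 stayed the same. List members named without passing in the fit of all groups, and genes named from fits chosen after seeing the data, were not part of these checks.

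The 6 arrays of a comparison split in 10 ways, the real one included, too few for a share under 0.05. The real count and the highest other were 3 and 0 for EAA against the reference on day 1 (1 of 10 as large), 0 and 12 on day 5 (10), 0 and 0 for MEA on day 1 (10), 1456 and 3652 on day 5 (2), 3 and 0 for EAA against MEA on day 1 (1), 526 and 2997 on day 5 (4). Between the days they were 4220 and 0 in the reference, 4975 and 0 with EAA and 535 and 0 with MEA (1 each). On the day 1 arrays alone EAA gave 193 and 1 (1), and without the MEA day 5 group EAA on day 5 gave 216 and 284 (2), so another split of the same arrays called more probe sets than the real one.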

Other observations

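Some gene families, formed from symbols after the annotation was read, passed camera in comparisons not described above. The cold and late embryogenesis family of 8 genes had a median EAA interaction of 0.70 between the days (adjusted p = 0.0282), the 10 nuclear photosystem and light harvesting genes one of -0.32 (adjusted p = 0.0248) and the 69 chloroplast-encoded genes one of -0.13 (adjusted p = 0.00857). The 9 ATG8 autophagy genes had a median MEA interaction of 0.31 (adjusted p = 0.0481), and the chloroplast-encoded genes a median of 0.05 for EAA against the reference on day 1 (adjusted p = 0.0198). With an estimated correlation these had an adjusted p of 0.953 to 0.973, with fry one of 0.369 to 0.871, and no single member of them passed in these contrasts. The EAA interactions include EAA day 5 replicate 1, with an actin 3' to 5' difference of 2.78 against 1.67 to 2.03 in the reference arrays. The MEA interaction includes MEA day 5 replicates 1 and 3, which lay near the day 1 arrays (positions 0.15 and 0.06) and had actin differences of 2.88 and 2.30. The 25S ribosomal RNA control probe set ranged from 6.85 (EAA day 1 replicate 3) to 11.31 (reference day 5 replicate 2) in log2 signal. Reference day 1 replicate 2 stood at 11.24 and MEA day 1 replicate 2 at 10.93, while the other reference arrays lay at 7.05 to 7.74.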
